A study of Homo sapiens with 12 samples.

How the data were processed

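Total RNA was sequenced from 12 libraries of the human lines THP-1, matured with PMA into macrophage-like cells, and EA.hy926, an endothelial hybrid. The 4 groups were THP-1 control, THP-1 with LDL, EA.hy926 control and EA.hy926 with LDL, each with 3 libraries labelled biological replicates, and every library was used. LDL was given at 100 µg/mL for 24 h in serum-free medium, RPMI-1640 for THP-1 and DMEM for EA.hy926, so line and medium cannot be told apart. The labels name the SKYEasy kit for RNA isolation and the VAHTS Universal V8 kit for library preparation. Whether poly(A) RNA was selected or ribosomal RNA removed is not given in the sources used here. Nothing in the labels says how the replicate dishes were kept apart beyond the words biological replicate, and p-values measure the spread between these libraries.

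The submitters' processing notes name FastQC, MultiQC, STAR, HTSeq and DESeq2 and the build GRCh38. Their versions, the annotation release, the strand setting and any filter are not given in the sources used here. The deposited values are a signal in normalised counts, gene read counts that the authors divided by one size factor per library. Checked on the values, each was a whole multiple of its library's smallest value above 0, in 100% of cases within a tolerance of 0.001, so whole reads could be recovered. The table held 20117 genes, 1742 of them at 0 in all 12 libraries, and 17210 had a gene symbol. Zeros often filled a whole group: 168 EA.hy926 genes at 10 to 15 normalised counts in one group had 0 reads in all 3 libraries of the other and 0 such genes had a total of 1 to 6 reads. A filter before the gene lists were joined may have made such zeros, but no source used here describes one. It was no plain limit per group, since in the same window 29 and 33 THP-1 genes had 0 reads in the control and LDL libraries and 6 and 19 had 1 to 6, and C3 was kept at 0.752 in EA.hy926 control. A group at 0 is therefore called listed at 0, and no fold is given against it. Reads shared by near-identical genes (the CXCL1, CXCL2 and CXCL3 chemokines, HLA genes, metallothioneins, histones) and reads of overlapping antisense genes may have been dropped or misassigned, which the table cannot show. Gene symbols were taken by gene identifier from a separate list of gene names, which matched 20104 genes, and coordinates from GENCODE 29.

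Recovered depth ran from 4.32 M reads in EA.hy926 LDL replicate 2 to 11.0 M in THP-1 control replicate 2. The deposited totals were 8.01 ± 0.103 M in EA.hy926 control, 8.43 ± 0.245 M in EA.hy926 LDL, 7.22 ± 0.0557 M in THP-1 control and 9.15 ± 0.0599 M in THP-1 LDL (SD, n = 3). One read counted as 0.653 to 1.91 normalised counts, which limits the precision of low values. No molecular identifiers are named in the sources used here, and the exact limits given for shares of genes cover counting error only. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 1.85 to 18.5 over genes with at least 20 reads), so none was counted as a duplicate. The pairs of THP-1 control libraries were closest, at 1.85, 2.36 and 2.07. This measure cannot tell separate dishes from repeat libraries of the same dish.

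A study of 3 against 3 has a smallest exact p of 0.1, so the tests below borrow spread across genes. These tests were chosen before the data were examined. Each line was fitted alone with limma 3.58.1 (R 4.3.3) on log2 of the deposited value plus 1, with an intensity trend, two-sided, on genes with a mean of at least 10 in a group. Adjustment followed Benjamini and Hochberg with a threshold of 0.05. The difference between the lines was tested as an interaction in a fit of the 12 libraries, on genes with a mean of at least 10 in a group of each line. Overlap of the calls was tested with Fisher's exact test across genes. The 31 gene lists and 7 lists of cell type markers were tested with camera at a preset correlation of 0.01, for lists with at least 5 measured genes. Camera with an estimated correlation and fry were run beside it. Levels in the control libraries are given with no test.

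Genes were named by a rule. In each line it took the 8 largest rises and the 8 largest falls among genes with a symbol, an adjusted p past the threshold, a mean of at least 50 in a group and no overlap between LDL and control libraries. It also took a panel of 15 genes whatever their result, among them HMGCS1, SQLE, INSIG1, ABCA1, ABCG1, MYLIP, PLIN2, CD36, ANGPTL4, PDK4, ACTB and VIM. Further genes were up to 4 members of each list with the smallest adjusted p, and for the difference between the lines the 5 largest in each direction under the same limits, with the mean of 50 needed in a group of each line. Some genes met by these rules and a gene list are not reported here. Chosen after their values were seen were RN7SL1, MALAT1, TLR4, CD14, LY96, MSR1, the histone genes, MT-RNR1 and MT-RNR2 in THP-1, C3, CXCL1, TNFRSF9, BIRC3, the genes given as examples of shared changes and the genes marked in the plot of fold changes. CH25H was chosen once the lists had been seen, before its own values were. The adjustment of Fisher's test over 8 tests was added after the results were seen.

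The alternatives tried were pseudocounts of 0.5 and 5, no minimum mean and a minimum of 50, TMM, median-of-ratios and quantile scaling, and a block for the labels' replicate number. Others were limma without the trend, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, the 12 libraries in one fit, a minimum log2 fold change of 1, an adjusted p threshold of 0.1 and each library left out in turn. Genes at 0 in a whole group left out and the level of RN7SL1 as a covariate were added after seeing the data. On simulated data made from the recovered reads, limma found 143 of 200 genes changed 2-fold in THP-1 (71.5%) with 11 false calls, and 137 of 200 in EA.hy926 (68.5%) with 10 false calls. At 1.5-fold it found 52.5% in THP-1 and 23.5% in EA.hy926, and at 4-fold 92.0% in both. The interaction found 95 of 153 genes at 2-fold, 2 of 152 at 1.5-fold and 140 of 148 at 4-fold. A list raised on simulated data was found in both lines, with 0 of the other lists called. The simulated genes were drawn independently of each other, so this run does not show how camera treats lists whose genes move together. In THP-1 at 2-fold it changed 200 of 15900 genes, whereas 64.5% of genes passed in the real fit. Its shares found and false calls therefore do not describe a fit in which most genes change. The series title names cell mechanics, and no such measurement is among the values used here.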

Results

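Bulk RNA sequencing was deposited for 12 libraries from 2 human lines kept in culture. THP-1 is a monocytic leukaemia line, turned here into macrophage-like cells with the phorbol ester PMA. EA.hy926 is a hybrid of HUVEC, which are endothelial cells of the umbilical vein, with the lung carcinoma line A549. Dishes of each line received serum-free medium alone or the same medium with 100 µg/mL of native low-density lipoprotein (LDL) from donors with cardiovascular disease, for 24 h. Each of the 4 groups held 3 libraries labelled as biological replicates, and the series title names the mechanics of both cell types as its subject. The depth recovered from the values was 7.97, 7.24 and 6.88 M reads for EA.hy926 control replicates 1 to 3 and 6.28, 4.32 and 7.78 M for the EA.hy926 LDL replicates. For THP-1 it was 8.25, 11.0 and 7.75 M reads in the control replicates and 7.96, 6.98 and 6.23 M in the LDL replicates. The non-coding RNA RN7SL1, the RNA of the signal recognition particle, took 8.90% to 12.7% of EA.hy926 control reads and 9.52% to 14.4% of EA.hy926 LDL reads. In THP-1 its share was 1.74% to 2.07% with control medium and 2.15% to 3.08% with LDL, and that of the nuclear RNA MALAT1 was 1.57% to 1.73% and 3.15% to 3.35%.

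The control libraries were first compared for the levels of receptors and markers, as values with no test. THP-1 control libraries carried the macrophage genes CSF1R at 9378 ± 656, CYBB at 5605 ± 109 and ITGAM at 4876 ± 179.9 normalised counts (SD, n = 3), and all 3 were listed at 0 in EA.hy926. EA.hy926 control libraries carried the endothelial genes CDH5 at 6668 ± 359, ENG at 5261 ± 403 and PECAM1 at 3098 ± 335. Of the 18 endothelial markers in the table, 16 reached a mean of 10 in EA.hy926 control libraries and 9 did in THP-1. Of the 10 lung epithelial markers in the table, listed for the A549 parent, 6 reached a mean of 10 in EA.hy926 control libraries and 2 did in THP-1. The highest in EA.hy926 were KRT7 at 5457 ± 114 and KRT18 at 4154 ± 418, while KRT19, ELF3 and AKR1C1 were listed at 0 there. The lipoprotein and scavenger receptors CD36, OLR1, CXCL16 and VLDLR were listed at 0 in EA.hy926 and at 4541 ± 121, 194 ± 8.93, 111 ± 10.0 and 1058 ± 20.7 in THP-1. MSR1, another scavenger receptor, stood at 3502 ± 88.3 in THP-1 and 154 ± 24.0 in EA.hy926, and STAB1 at 930.5 ± 48.8 and 3863 ± 1092. A value of 0 for a whole group does not show absence in this table: CD68, a marker of macrophages, was listed at 0 in all 3 THP-1 control libraries. Line and medium differed together, so neither can be read apart from the other.

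The first comparison asked how 24 h with LDL changed the transcripts of THP-1 macrophages. Among the 8 largest rises were chemokine, costimulatory and interferon-induced genes. CXCL10 (ENSG00000169245.6, chromosome 4, 76021117.0 to 76023497.0, minus strand, build GRCh38), a chemokine that draws activated T cells, went from 7.95 ± 2.32 to 10425 ± 1194 normalised counts (SD, n = 3 per group), a log2 fold change of 10.21 ± 0.15 (SE; limma adjusted p = 3.3e-14). CD80, a ligand that costimulates T cells, went from 3.38 ± 1.32 to 4887 ± 131, and CXCL11, another chemokine, from 0.653 ± 1.13 to 1187 ± 139. The chemokine receptor gene CCR7 went from 0.290 ± 0.503 to 791 ± 59.1 and the interferon-induced IFI44L from 24.8 ± 5.40 to 14068 ± 1531. IDO1 (ENSG00000131203.13, chromosome 8, 39902275.0 to 39928444.0, plus strand), which encodes an enzyme that breaks down tryptophan, was listed at 0 in the 3 control libraries and at 2154, 2234 and 1811 in the 3 LDL libraries. TNFAIP6, a secreted protein that binds hyaluronan, and the chemokine CXCL13 were likewise listed at 0 with control medium, and at 1249, 1595 and 1229 and at 906, 1084 and 831 with LDL. No fold is given against a group listed at 0.

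The 8 largest falls in THP-1 had log2 fold changes of -5.89 for FGL1, -5.70 for MAMDC2, -5.50 for PHACTR3, -5.31 for TRDN, -4.87 for CX3CR1, -4.85 for ZNF385B, -4.72 for MMRN2 and -4.54 for FABP4. CX3CR1, the receptor of the chemokine fractalkine, fell from 1110.2 ± 72.3 to 37.3 ± 6.48 (limma adjusted p = 3.1e-12). FABP4 (ENSG00000170323.9, chromosome 8, 81478419.0 to 81483263.0, minus strand), a carrier of fatty acids in macrophages and fat cells, fell from 1411 ± 130.5 to 59.9 ± 9.17 (adjusted p = 3.1e-12). PHACTR3, which binds actin and protein phosphatase 1, fell from 239 ± 4.47 to 5.54 ± 4.53. For each of these 16 rises and falls, no LDL library overlapped the control libraries, as the rule for naming them required.

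In all, 10425 of the 16167 genes tested in THP-1 (64.5%) passed the adjusted p threshold of 0.05 in limma, 5743 higher and 4682 lower with LDL. Of these, 2736 rose and 1765 fell by at least 1 on the log2 scale, and 131 were listed at 0 throughout one group. Without any adjustment 10931 genes passed 0.05. The median log2 fold change of all genes tested was 0.08 with the deposited scaling, -0.02 with TMM, 0.01 with median-of-ratios and -0.08 with quantile normalization. With quantile normalization 4636 genes were higher and 5728 lower, so the balance between rises and falls depends on the scaling.

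Interferon-induced genes rose together in THP-1: all 29 measured members of the list were higher with LDL, with a median log2 fold change of 4.61 (camera adjusted p = 8.5e-22, and 0.0155 with an estimated correlation). RSAD2, an antiviral enzyme, rose from 45.6 ± 3.72 to 7123 ± 695, IFI44 from 84.2 ± 7.69 to 4385 ± 158 and IFIT3, which binds viral RNA, from 106 ± 2.06 to 3542 ± 189.9. Targets of the transcription factor NF-kB and inflammatory cytokines rose in 27 of 28 cases and fell in 1, with a median of 4.71 (adjusted p = 4.0e-17, and 0.0155 with an estimated correlation). CXCL8, a chemokine for neutrophils, rose from 53.1 ± 7.49 to 19766 ± 3156, the cytokine gene IL1B from 230.3 ± 5.62 to 8664 ± 754, the mitochondrial superoxide dismutase gene SOD2 from 1148 ± 11.8 to 33639 ± 1877 and TNFAIP3, an inhibitor of NF-kB, from 612 ± 21.5 to 11122 ± 215. Immediate early genes rose in 14 of 18 cases and fell in 0, with a median of 1.00 (camera adjusted p = 1.6e-05; adjusted p = 0.343 with an estimated correlation). ATF3 rose from 1581 ± 24.8 to 7005 ± 266, IER3 from 57.2 ± 5.84 to 1262 ± 164 and DUSP1, a phosphatase of MAP kinases, from 4079.6 ± 198 to 15321 ± 506. The inflammasome list had 9 members higher and 4 lower of 13 (median 0.74, camera adjusted p = 0.0481; adjusted p = 0.213 with an estimated correlation), and AIM2, a sensor of DNA, rose from 11.2 ± 2.01 to 490.4 ± 8.22 and CASP1 from 153 ± 13.3 to 966 ± 28.3. This last call was lost without LDL replicate 1 (adjusted p = 0.0788) or 3 (0.0520), with quantile normalization (0.0551), without the trend of limma (0.108) and with all 12 libraries in one fit (0.0692).

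Genes of endothelial adhesion and vascular tone went both ways in THP-1, 8 higher and 5 lower of 17 measured (median 0.32, camera adjusted p = 0.499). ICAM1 (ENSG00000090339.9, chromosome 19, 10270835.0 to 10286615.0, plus strand), an adhesion molecule for leukocytes, rose from 624 ± 28.8 to 20719 ± 1307 and VCAM1, another one, from 3.34 ± 1.08 to 531 ± 99.5. EDN1, the precursor of the vasoconstrictor endothelin, rose from 7.49 ± 2.11 to 147 ± 8.80, and F3, tissue factor, from 85.1 ± 15.02 to 331 ± 21.0. The macrophage markers had 7 members higher and 6 lower of 17 (camera adjusted p = 0.925), with PTPRC from 2962 to 6241 and MS4A7 from 595 to 1942 among the rises and ITGAM from 4876 to 2497 among the falls. Genes of alternative polarisation had 4 higher and 5 lower of 11 (adjusted p = 0.904), among them the haemoglobin receptor gene CD163, which rose from 379 ± 9.93 to 971 ± 36.5, and STAB1, which fell from 930.5 ± 48.8 to 248 ± 28.2. The median of this list was 0.17, while its mean was -0.27 and the test pointed down.

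Genes of cholesterol synthesis fell in THP-1. Of the 20 enzymes, all measured, 18 were lower with LDL and 1, LSS, was higher, with a median log2 fold change of -1.21 (camera adjusted p = 4.3e-07, and 0.0350 with an estimated correlation). MSMO1 (ENSG00000052802.13, chromosome 4, 165327623.0 to 165343160.0, plus strand) fell from 725 ± 13.6 to 148 ± 27.8, FDFT1 from 1893 ± 80.1 to 584 ± 50.9 and HMGCS1 from 1028 ± 34.8 to 450.0 ± 60.6 (log2 -1.20 ± 0.091). LSS, lanosterol synthase, rose from 369.5 ± 20.4 to 1319 ± 117. SQLE, squalene epoxidase, went from 4099 ± 273 to 4679 ± 487, a log2 change of 0.19 ± 0.080 that did not pass the threshold (limma adjusted p = 0.0566) and was -0.33 with quantile normalization (adjusted p = 9.3e-04). On the list of cholesterol uptake and SREBP regulation, 3 members were higher and 8 lower of 14 (median -0.26, camera adjusted p = 0.119). INSIG1, which holds the SREBP complex in the endoplasmic reticulum, fell from 1810.1 ± 80.5 to 920.2 ± 62.9, and SREBF2, the SREBP gene of cholesterol synthesis, from 2398 ± 127 to 1329 ± 96.8.

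Fatty acid synthesis and desaturation genes also fell in THP-1, 9 lower and 3 higher of 15 (median -0.68, camera adjusted p = 0.0162; adjusted p = 0.171 with an estimated correlation). The desaturase genes FADS2, SCD and FADS1 fell from 2203 to 182, from 9136 to 2196 and from 1283 to 262. ACSL1, which activates fatty acids, rose from 1039 ± 11.6 to 12270.4 ± 555. Targets of PPAR and genes of fatty acid oxidation had 12 members lower and 4 higher of 18 (median -0.49, adjusted p = 0.0149; adjusted p = 0.171 with an estimated correlation). CD36, which binds oxidised LDL and fatty acids, fell from 4541 ± 121 to 1726 ± 248, PDK4, an inhibitor of pyruvate dehydrogenase, from 45.4 ± 5.29 to 0.385 ± 0.668 and ACADM from 679 ± 42.8 to 332 ± 35.2. ANGPTL4, an inhibitor of lipoprotein lipase, rose from 1.69 ± 1.56 to 17.5 ± 2.84 (limma adjusted p = 9.9e-05), a call lost with the level of RN7SL1 as a covariate (log2 1.87, adjusted p = 0.152). LXR targets and efflux genes went both ways, 5 higher and 5 lower of 15 (camera adjusted p = 0.925), and while their median and mean were 0.12 and 0.17 the test pointed down. ABCA1 (ENSG00000165029.17, chromosome 9, 104781002.0 to 104928237.0, minus strand), which exports cholesterol to apolipoprotein A-I, rose from 6471 ± 64.9 to 19961 ± 472 (log2 1.62 ± 0.059), ABCG1, which exports it to high-density lipoprotein, from 747 ± 19.2 to 1300.2 ± 79.3, and the LXR alpha gene NR1H3 from 186 ± 11.2 to 1002 ± 73.4. SCARB1, the receptor of high-density lipoprotein, fell from 2113 ± 101 to 647 ± 36.2, and MYLIP, a ubiquitin ligase, went from 257 ± 9.03 to 257 ± 17.3 (adjusted p = 0.996).

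Lipid droplet genes went both ways in THP-1, 6 higher and 6 lower of 16 (camera adjusted p = 0.727). PLIN2, which coats lipid droplets, fell from 3029 ± 75.2 to 2362 ± 60.6 (log2 -0.36 ± 0.057, limma adjusted p = 1.1e-04), MGLL, a lipase of monoglycerides, rose from 28.5 ± 7.05 to 629 ± 46.3 and G0S2, an inhibitor of the main triglyceride lipase, from 318 ± 11.9 to 809 ± 119.6. Scavenger and lipoprotein receptors had 8 members higher and 8 lower of 17 (camera adjusted p = 0.727). CXCL16 rose from 111 ± 10.0 to 952 ± 20.02 and VLDLR from 1058 ± 20.7 to 2582 ± 105, while SORL1 fell from 7533 ± 155 to 1442 ± 81.1. Lysosomal genes rose in 12 of 21 cases and fell in 3 (median 0.51, camera adjusted p = 0.0134; adjusted p = 0.487 with an estimated correlation). This call was lost with quantile normalization (median 0.17, adjusted p = 0.179) and with the RN7SL1 covariate (0.112). The protease genes CTSS, CTSL and CTSB rose from 4005 to 11245, from 4613 to 12383 and from 5782 to 11763.

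**Figure D1:**
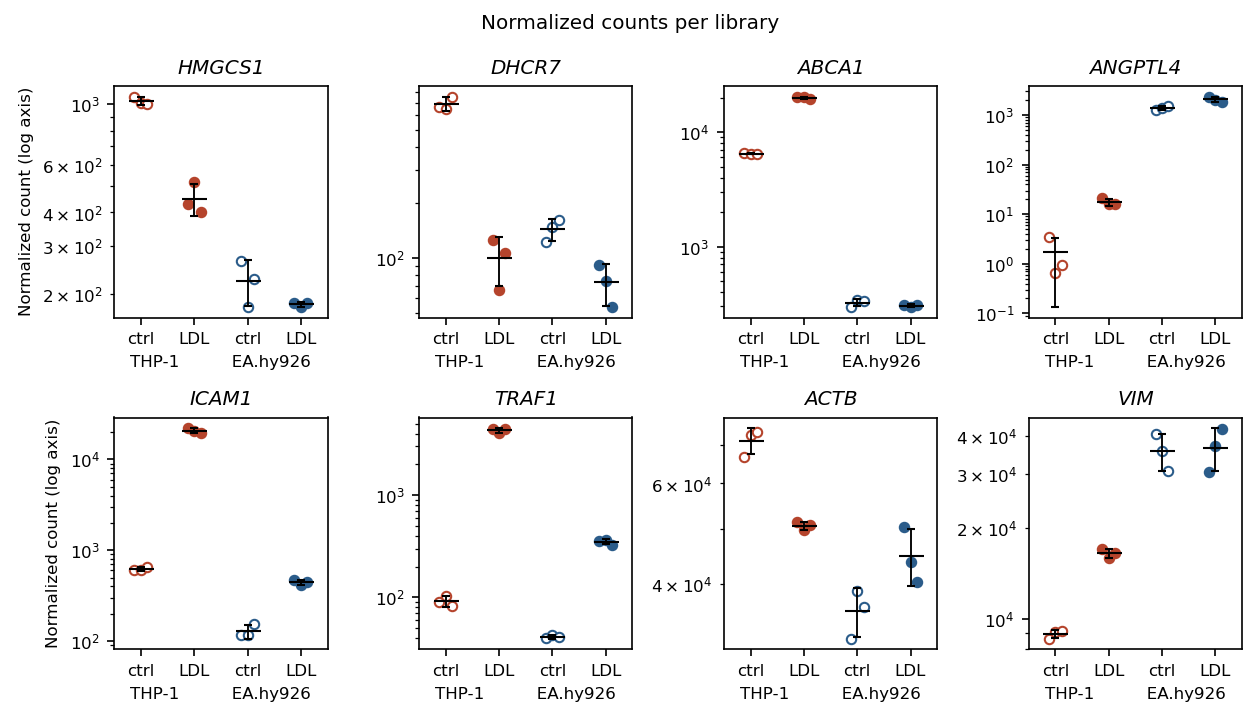
Normalised counts per library (log axes) of HMGCS1, DHCR7, ABCA1, ANGPTL4, ICAM1, TRAF1, ACTB and VIM in the 4 groups of 3 libraries, with open circles for control, filled circles for LDL, horizontal bars for means and error bars for the SD. HMGCS1 went from 1028 to 450.0 in THP-1 and from 224 to 184 in EA.hy926, whereas ABCA1 rose in THP-1 and stood at 324 and 305 in EA.hy926.

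Cytoskeletal genes, which bear on the mechanics named in the series title, fell in THP-1. Of 53 measured genes of the actin and actomyosin cytoskeleton, 37 were lower and 7 higher with LDL (median -0.37, camera adjusted p = 1.4e-06; adjusted p = 0.191 with an estimated correlation). The size of this median depends on the scaling: it was -0.47 with TMM and -0.83 with quantile normalization. ACTB (ENSG00000075624.17, chromosome 7, 5527147.0 to 5563784.0, minus strand), beta-actin, fell from 71260.2 ± 3803 to 50548 ± 832, a log2 change of -0.49 ± 0.078 (limma adjusted p = 1.1e-04). CNN2, which binds actin, fell from 1887 ± 67.0 to 637 ± 29.3, CAPG, which caps filaments, from 1497 ± 18.4 to 697 ± 69.1, ENAH, which lengthens them, from 287 ± 19.6 to 51.4 ± 11.3 and DSTN, which severs them, from 289 ± 33.3 to 83.0 ± 1.24. Intermediate filaments, lamins and tubulins fell in 14 of 21 cases and rose in 3 (median -0.76, camera adjusted p = 9.1e-05; adjusted p = 0.0942 with an estimated correlation). The tubulin gene TUBA1A fell from 1638 ± 59.1 to 233 ± 38.8, LMNB1, a lamin of the nuclear envelope, from 1943 ± 25.4 to 552 ± 31.7 and STMN1, which destabilises microtubules, from 1734 ± 47.0 to 339 ± 23.3. VIM, the intermediate filament vimentin, was among the rises and went from 8952 ± 274 to 16516 ± 572 (log2 0.88 ± 0.062, adjusted p = 5.6e-08).

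Adhesion and signalling genes of the cytoskeleton went both ways in THP-1. Integrins and focal adhesion genes had 19 higher and 13 lower of 33 (camera adjusted p = 0.523), with the integrin genes ITGB3 and ITGA5 up from 27.2 to 647 and from 5870.1 to 19889, and VCL, vinculin, down from 2297 ± 43.5 to 469 ± 29.1. YAP and SRF/MRTF targets had 14 higher and 5 lower of 27 (median 0.24, adjusted p = 0.108), with the receptor kinase gene AXL up from 204 to 3001 and TEAD1, the DNA-binding partner of YAP, up from 450.3 to 1211. Matrix genes had 16 higher and 6 lower of 27 (median 0.43, adjusted p = 0.0566). The metalloproteinase genes MMP19, MMP7 and MMP9 rose from 93.3 to 3203, from 23.4 to 717 and from 12597 to 41890.2. Junction genes had 8 higher and 5 lower of 15 (adjusted p = 0.385). CLDN1, claudin-1, rose from 2.90 ± 0.335 to 659 ± 85.5 and JUP, plakoglobin, fell from 399.6 ± 33.3 to 131 ± 13.7.

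Genes of cell division fell in THP-1, all 32 of the S and M phase list (median -1.59, camera adjusted p = 6.6e-18, and 0.0350 with an estimated correlation). MKI67 fell from 2111 ± 42.2 to 405 ± 20.5, TOP2A from 2311 ± 136 to 485 ± 28.0 and CDC20, an activator of mitotic exit, from 1904 ± 79.8 to 488 ± 23.3. Cytosolic ribosomal protein genes fell in 43 of 43 cases (median -0.93, adjusted p = 3.0e-18; adjusted p = 0.199 with an estimated correlation), as with RPS23 from 2003 ± 166 to 674 ± 61.2 and RPL7 from 1782 ± 102 to 631 ± 54.0. All 13 mitochondrially encoded mRNAs fell (median -1.75, adjusted p = 1.0e-06; adjusted p = 0.227 with an estimated correlation), with MT-ND4 going from 739.8 ± 76.6 to 141 ± 17.6. Nuclear genes of oxidative phosphorylation fell in 23 of 27 cases (median -0.59, adjusted p = 1.0e-06, and 0.0410 with an estimated correlation), as with UQCRH from 602 ± 21.2 to 228 ± 27.6 and COX5A from 499 ± 34.8 to 241 ± 8.49. Hypoxia and glycolysis genes had 16 higher and 7 lower of 27 (median 0.53, adjusted p = 0.0481; adjusted p = 0.428 with an estimated correlation). This call was lost without LDL replicate 1 (adjusted p = 0.0886), with quantile normalization (0.136), without the trend of limma (0.0627), with all 12 libraries in one fit (0.0692) and with the RN7SL1 covariate (median 0.24, adjusted p = 0.172). HK2, hexokinase 2, rose from 427 ± 18.2 to 2959 ± 96.8, VEGFA from 1194 ± 65.4 to 5661 ± 517 and the glucose transporter gene SLC2A1 from 1691 ± 126 to 4528 ± 264.

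Stress lists differed in direction in THP-1. Genes of the unfolded protein and amino acid stress response rose in 19 of 25 cases and fell in 5 (median 1.27, camera adjusted p = 7.8e-05; adjusted p = 0.227 with an estimated correlation). SESN2, which dampens growth signalling when amino acids are short, rose from 354 ± 5.62 to 2521 ± 204, and SLC3A2, a chain of amino acid transporters, from 2869 ± 171 to 13659.7 ± 1097. Heat shock proteins fell in 10 of 13 cases and rose in 1 (median -0.71, adjusted p = 7.2e-04; adjusted p = 0.0942 with an estimated correlation), as with the chaperone gene HSPA8 from 10579 ± 186 to 3998 ± 307. NRF2 and oxidative stress genes had 12 higher and 6 lower of 24 (adjusted p = 0.154), with the cystine transporter gene SLC7A11 up from 332 to 5044 and CAT, catalase, down from 1085 to 274. Metallothioneins and metal handling had 5 higher and 3 lower of 11 (adjusted p = 0.640), with the ferritin heavy chain FTH1 up from 3344 to 7141 and the light chain FTL down from 9356 to 5827. Targets of p53 and apoptosis genes had 11 higher and 4 lower of 18 (adjusted p = 0.0851), with the survival gene MCL1 up from 7835 to 21319 and SESN1 down from 1352 to 566.

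Markers of other cell types were examined in the same THP-1 libraries. The endothelial markers had 1 member higher, PECAM1 from 1084 to 1367, and 4 lower of 9 measured (median -0.46, camera adjusted p = 0.0604), among them MMRN2 from 145 to 4.75 and ROBO4 from 54.3 to 7.67. The call of PECAM1 was lost with quantile normalization (limma adjusted p = 0.194) and the RN7SL1 covariate (0.224), and that of ROBO4 with the covariate (0.111). Fibroblast and smooth muscle markers had 3 higher of 5, PDGFRA from 81.3 to 177, PDGFRB from 11.0 to 23.7 and MYH11 from 6.17 to 31.2 (adjusted p = 0.285). The PDGFRB call was lost with quantile normalization (0.0571) and the covariate (0.475). Of the lymphocyte markers TRAC fell from 225 to 130.4, a call lost with the covariate (0.0791), and NKG7 went from 9.86 to 15.8 (limma adjusted p = 0.0952). Among hepatocyte markers SERPINA1, which macrophages also express, rose from 195 to 499.9, and among lung epithelial ones CLDN1 and MUC1 rose, MUC1 from 23.4 to 79.9. No erythroid or platelet marker reached the filter in THP-1. Of the 17 lists past the threshold of camera in THP-1, the 5 that also held with an estimated correlation were interferon, NF-kB, cell cycle, cholesterol synthesis and oxidative phosphorylation. In fry, which tests whether the genes of a list move on balance 1 way and compares them with no other genes, the adjusted p in THP-1 was 1.1e-04 for actin, 1.0e-04 for ribosomal proteins and 1.3e-05 for the unfolded protein list. The counts adjusted over the list alone were those given, except for 2 higher in cholesterol synthesis, 12 higher in p53 targets, and 6 lower in YAP and SRF/MRTF targets, 6 lower in junctions and 7 lower in macrophage markers. The non-coding RNAs RN7SL1 and MALAT1, chosen after their values were seen, were higher in the LDL libraries by 0.71 and 1.34 on the log2 scale, alongside every list described here, but RN7SL1 was at -0.31 with quantile normalization. With the level of RN7SL1 as a covariate, an alternative chosen after seeing the data, 6417 genes passed in THP-1. The RN7SL1 share of THP-1 reads did not overlap between control (1.74% to 2.07%) and LDL libraries (2.15% to 3.08%). The covariate thus follows treatment in THP-1, and a call lost with it does not tell whether LDL changed the gene or list.

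In the second comparison, of LDL with control medium in EA.hy926, the 8 largest rises included NF-kB targets and the haem-degrading enzyme HMOX1. TRAF1 (ENSG00000056558.11, chromosome 9, 120902393.0 to 120929173.0, minus strand), an adaptor of tumour necrosis factor receptors, rose from 41.0 ± 1.55 to 349.9 ± 19.8 normalised counts (SD, n = 3 per group), a log2 fold change of 3.06 ± 0.16 (SE; limma adjusted p = 1.3e-06). HMOX1 (ENSG00000100292.18, chromosome 22, 35380361.0 to 35394214.0, plus strand) rose from 659.7 ± 3.33 to 2238 ± 115 (log2 1.76 ± 0.093, adjusted p = 1.3e-06). CXCL8 rose from 36.9 ± 11.9 to 194 ± 19.7, RELB, an NF-kB subunit, from 56.6 ± 12.0 to 230.2 ± 29.3, the adhesion gene ICAM1 from 129 ± 22.2 to 442 ± 23.3, TNFAIP3 from 29.2 ± 12.2 to 85.5 ± 10.4 and the chemokine gene CXCL2 from 90.0 ± 26.0 to 238 ± 26.7. MT-TM, the mitochondrial tRNA of methionine, rose from 18.3 ± 3.51 to 50.7 ± 8.67. The largest falls were in the mitochondrial ribosomal RNAs MT-RNR1 (chromosome M, 648 to 1601), from 960.3 ± 529 to 86.3 ± 49.4 and a log2 fold change of -3.50 ± 0.40 (adjusted p = 1.5e-04), and MT-RNR2, from 1352 ± 478 to 189.7 ± 111 (log2 -2.95 ± 0.35). DHCR7, an enzyme of cholesterol synthesis, fell from 144 ± 19.6 to 73.2 ± 18.8. PALMD fell from 72.6 ± 13.1 to 31.7 ± 8.70, RAPGEF5 from 308 ± 21.3 to 185 ± 28.3, the lipid transporter gene ABCA8 from 228 ± 15.9 to 139 ± 27.8 and ST3GAL5, which makes the ganglioside GM3, from 706 ± 20.3 to 437 ± 17.3. 

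In limma, 285 of the 14202 genes tested in EA.hy926 passed the adjusted p threshold, 124 higher and 161 lower, and 1583 passed 0.05 without adjustment. Of the 285, 186 were listed at 0 in all 3 libraries of one group, 44 higher and 142 lower with LDL, with levels below 50 in the other group. The other 99 comprised 80 rises and 19 falls. Without a single library that number was 69, 56 and 67 for control replicates 1 to 3 and 65, 47 and 148 for LDL replicates 1 to 3. It was 286 with all 12 libraries in one fit, 55 without the trend of limma and 45 with a replicate block, 40 higher and 5 lower. It was 48, 41 higher and 7 lower, when genes at 0 were left out of the fit, an alternative chosen after seeing the data. With a minimum mean of 50 the whole count was 45, with no minimum 466 and with all 12 libraries in one fit 473.

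NF-kB targets and inflammatory cytokines rose in EA.hy926, 11 of 20 measured members and 15 when adjusted over the list alone (median 0.88, camera adjusted p = 7.0e-24; adjusted p = 0.0645 with an estimated correlation). SOD2 rose from 911 ± 78.6 to 1813 ± 45.4. NRF2 and oxidative stress genes rose in 6 of 25 cases, and in 16 when adjusted over the list alone (median 0.31, adjusted p = 7.3e-14; adjusted p = 0.0645 with an estimated correlation). The ferritin heavy chain FTH1 rose from 3092 ± 240.4 to 5620.4 ± 42.4 and OSGIN1, an NRF2 target, from 513 ± 43.0 to 998 ± 132. Among metallothioneins and metal handling genes FTH1 and the transferrin receptor gene TFRC rose, 2 of 8 and 5 over the list alone (median 0.50, adjusted p = 7.0e-05; adjusted p = 0.239 with an estimated correlation), TFRC from 1102 ± 51.2 to 1515 ± 72.6. Of 16 immediate early genes FOSL1 rose, from 1387 ± 122 to 2104 ± 47.8, and 3 did over the list alone (median 0.40, adjusted p = 9.6e-08; adjusted p = 0.324 with an estimated correlation). Of 24 genes of the unfolded protein and amino acid stress response PPP1R15A, which lets translation resume, rose from 2924 ± 226 to 4079 ± 434 (list median 0.07, adjusted p = 0.0335; adjusted p = 0.440 with an estimated correlation). Of 14 genes of endothelial activation ICAM1 rose, and 3 did over the list alone (camera adjusted p = 0.0580). THBD, thrombomodulin, went from 5145 ± 705 to 7520.5 ± 1022 (limma adjusted p = 0.0761). The interferon list had 0 of 24 members past the threshold of limma, and 0 over the list alone (median 0.09, camera adjusted p = 0.488).

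Of 14 genes of cholesterol uptake and SREBP regulation 1 was lower in EA.hy926, and 2 over the list alone (camera adjusted p = 0.222). In cholesterol synthesis 2 of 20 were lower, DHCR7 among them (median -0.02, camera adjusted p = 0.360). HMGCS1 went from 224 ± 43.3 to 184 ± 3.53, SQLE from 439 ± 42.1 to 396 ± 16.8 and INSIG1 from 351 ± 44.7 to 388 ± 39.1, with limma adjusted p of 0.578, 0.690 and 0.723. Among 15 genes of fatty acid synthesis SCD fell from 525 ± 78.3 to 323 ± 20.7 (list median -0.20, camera adjusted p = 0.0115; adjusted p = 0.239 with an estimated correlation). ANGPTL4 rose from 1392 ± 124 to 2065 ± 268 (limma adjusted p = 0.0200), the 1 call among 14 PPAR targets and fatty acid oxidation genes (camera adjusted p = 0.276). The efflux gene ABCA1 went from 324 ± 23.9 to 305 ± 8.19, ABCG1 from 236 ± 44.9 to 261 ± 42.5 and MYLIP from 188 ± 36.5 to 177 ± 41.2, with limma adjusted p of 0.829, 0.777 and 0.884. Neither the 9 LXR targets nor the 13 lipid droplet genes nor the 8 scavenger receptors had a member past the threshold of limma, also over the list alone, and their camera adjusted p were 0.243, 0.188 and 0.296. PLIN2, CD36 and PDK4 were listed at 0 in EA.hy926. Lysosomal genes had 0 of 21 past the threshold of limma, with a median of 0.15 (camera adjusted p = 0.00447; adjusted p = 0.239 with an estimated correlation).

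None of the 53 actin and actomyosin genes passed the threshold of limma in EA.hy926, also over the list alone (median 0.02, camera adjusted p = 0.638). ACTB went from 35809.7 ± 3472 to 44779.9 ± 5099.9 (limma adjusted p = 0.555) and VIM from 35729 ± 4915 to 36714 ± 5912 (adjusted p = 0.961). Intermediate filaments, lamins and tubulins had 0 of 25 past the threshold, with a median of 0.09 (camera adjusted p = 0.0445; adjusted p = 0.239 with an estimated correlation). Of 27 matrix genes MMP9 rose from 2.48 ± 1.48 to 17.4 ± 4.40 and LOX, which crosslinks collagen, from 232 ± 6.28 to 361 ± 31.4, and 3 did over the list alone (camera adjusted p = 0.831). CLDN1 rose from 111 ± 16.9 to 209.7 ± 10.1 among 16 junction genes, with 2 higher and 1 lower over the list alone (adjusted p = 0.488). The integrin gene ITGAL was the 1 call of 31 focal adhesion genes, at 9.18, 12.1 and 9.28 in the control libraries and listed at 0 with LDL, with 1 higher and 1 lower over the list alone (adjusted p = 0.243). YAP and SRF/MRTF targets had 0 of 24 past the threshold of limma, also over the list alone (camera adjusted p = 0.215).

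Cell cycle genes in EA.hy926 had 0 of 32 past the threshold of limma (median 0.07, camera adjusted p = 0.188). So had heat shock proteins with 0 of 14 (adjusted p = 0.487) and hypoxia genes with 0 of 25 (adjusted p = 0.188), also over the lists alone. Ribosomal protein genes, nuclear genes of oxidative phosphorylation and mitochondrial mRNAs had 0 members past it, with list medians of 0.10, 0.14 and 0.36 and camera adjusted p of 0.0124, 0.00708 and 0.00447; with an estimated correlation the adjusted p were 0.629, 0.443 and 0.589. In the inflammasome list NLRP3 was listed at 0 in the control libraries and at 10.6, 15.3 and 13.4 with LDL, and TXNIP, an inhibitor of thioredoxin, fell from 2450.1 ± 255 to 1655 ± 76.3 (list adjusted p = 0.532). BCL2, the 1 call of 18 p53 targets and apoptosis genes, was at 3.06, 8.77 and 18.6 in the control libraries and listed at 0 with LDL (list adjusted p = 0.487). Of 3 measured genes of alternative polarisation TGM2, a transglutaminase, rose from 4961 ± 178 to 7035 ± 391. Endothelial markers had 0 of 16 past the threshold and 1 lower over the list alone (median -0.19, camera adjusted p = 0.0297; adjusted p = 0.239 with an estimated correlation), with PECAM1 from 3098 to 2313 and SOX18 from 391 to 232. Lung epithelial markers had CLDN1 higher of 6, and 2 over the list alone (median 0.23, adjusted p = 0.0104; adjusted p = 0.239 with an estimated correlation), with KRT7 from 5457 to 7136. The few measured markers of other cells did not pass in limma: the macrophage genes LAPTM5 from 689.9 to 798 and LYZ from 51.0 to 53.2, the lymphocyte gene TRAC from 29.3 to 27.9, the erythroid gene HBG2 from 18.9 to 19.2 and the smooth muscle gene ACTA2 from 162 to 176.

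Leaving out single libraries ended 17 of the 35 gene calls that the naming rule gave for EA.hy926, and the other 18 held in all 6 such fits. The highest adjusted p of limma were found without LDL replicate 2 for ABCA8 (0.264), ANGPTL4 (0.1204), CLDN1 (0.0579), PPP1R15A (0.289), RAPGEF5 (0.0913), TFRC (0.150), TGM2 (0.188) and TXNIP (0.0991). They were found without control replicate 2 for PALMD (0.259), RND3 (0.0695), SCD (0.111) and TNFAIP3 (0.0778), and without control replicate 3 for DHCR7 (0.220) and LOX (0.0719). For CCL2 the highest was 0.153, without LDL replicate 1, and for MT-TM 0.0594, without LDL replicate 3. Of the calls that held in these fits, FOSL1 was lost without the trend of limma (0.0901) and with all 12 libraries in one fit (0.0910). BCL2 was lost with a pseudocount of 5 (0.0841) and with quantile normalization (0.390), and MMP9 without genes at 0 (0.0745). Of the gene calls named in either line, 16 were lost without the trend, 14 with a replicate block, 13 without genes at 0 and 11 at a minimum mean of 50. The 14 were all in EA.hy926, among them DHCR7 (0.167), SCD (0.0847) and CCL2 (0.216). Of the 13 EA.hy926 lists past the threshold of camera 7 were likewise lost, with highest adjusted p of 0.121 for intermediate filaments and 0.163 for oxidative phosphorylation without control replicate 3. They were 0.0604 for lung epithelial markers without the same library, and 0.0917 for endothelial markers without control replicate 2. The highest for the unfolded protein list was 0.121 without LDL replicate 1, for mitochondrial mRNAs 0.275 without LDL replicate 2 and for ribosomal proteins 0.986 without LDL replicate 3. In these fits the median log2 fold change ran from 0.055 to 0.14 for unfolded protein and from 0.075 to 0.20 for oxidative phosphorylation. That of lung epithelial markers ran from 0.14 to 0.28. With quantile normalization the lists of intermediate filaments (0.332), unfolded protein (0.321) and ribosomal proteins (0.851) were lost as well. With a replicate block those of intermediate filaments (0.0942) and unfolded protein (0.0596) were lost. None of the 13 lists held with an estimated correlation, which ran from -0.039 for endothelial markers to 0.78 for mitochondrial mRNAs. A call lost in that test therefore does not by itself show that the genes of a list move together.

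**Figure D2:**
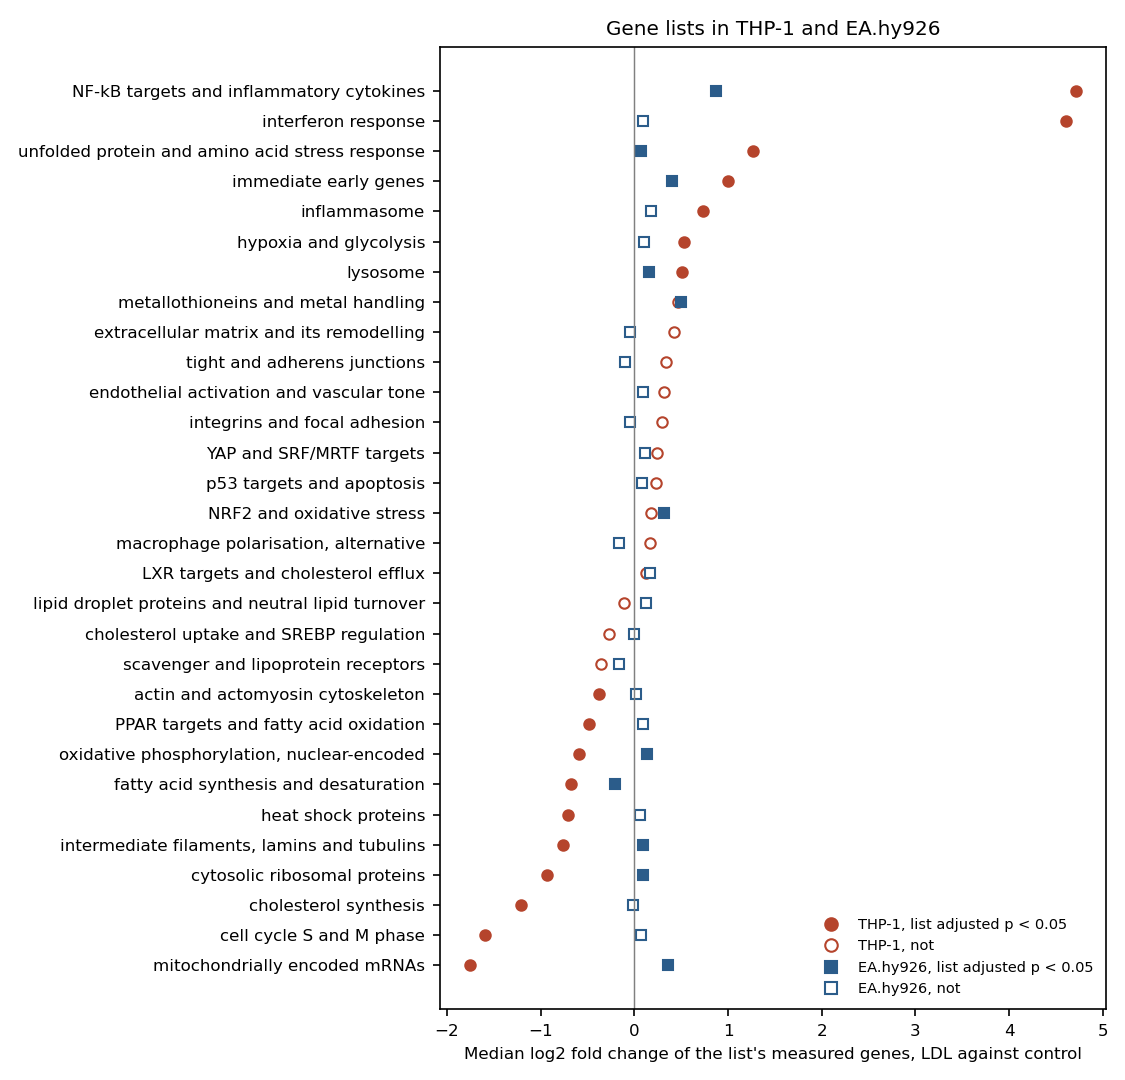
Median log2 fold change (horizontal axis, LDL against control) of the measured genes of the gene lists in THP-1 (circles) and EA.hy926 (squares), filled where the camera test of the list passed an adjusted p of 0.05. The NF-kB list lay at 4.71 in THP-1 and 0.88 in EA.hy926, and the interferon list at 4.61 and 0.09.

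The third comparison tested the difference between the responses of both lines, the THP-1 fold change minus that of EA.hy926. In limma 5901 of 12534 genes differed, 3154 towards a higher change in THP-1 and 2747 towards a lower one, and 127 of them were listed at 0 throughout a group. Among genes with a mean of 50 or more in a group of each line, the largest positive differences were in CD274, the immune checkpoint ligand PD-L1, with 8.67 ± 0.36 on the log2 scale (SE; adjusted p = 2.2e-12), CCL2, a chemokine for monocytes, with 7.12 ± 0.23, P3H2 with 6.99 ± 0.20, IFI27 with 6.80 ± 0.31 and the class II gene HLA-DRA with 6.69 ± 0.27. CD274 went from 2.22 to 1268 in THP-1 and from 182 to 190.5 in EA.hy926, P3H2 from 23.9 to 3487 and from 166 to 186, IFI27 from 5.46 to 708 and from 222 to 232, and HLA-DRA from 6.79 to 728 and from 156 to 138. CCL2 rose in both, from 3.34 to 859.6 and from 262 to 382, the latter a call lost without LDL replicate 1 (adjusted p = 0.153) and in each of the other 5 fits that left out 1 EA.hy926 library. The largest negative ones under the same limit were in MMRN2 (-4.51 ± 0.26), NRGN (-4.37 ± 0.21), RFLNB (-4.19 ± 0.24), BIN1 (-4.05 ± 0.24) and DYSF (-3.98 ± 0.18). DYSF, a protein of membrane repair, went from 978 to 57.1 in THP-1 and from 5688 to 5254 in EA.hy926, NRGN from 2397 to 124 and from 79.5 to 83.8, RFLNB from 639 to 52.9 and from 71.8 to 109, and BIN1, which bends membranes, from 204 to 12.0 and from 1189 to 1209.

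Of 7 lipid lists only cholesterol synthesis differed between the lines in camera. The adjusted p were 0.208 for cholesterol uptake, 0.0538 for fatty acid synthesis, 0.643 for LXR targets, 0.953 for lipid droplets, 0.363 for PPAR targets and 0.953 for scavenger receptors. Of single lipid genes HMGCS1 had a difference of -0.93 ± 0.18 on the log2 scale (limma adjusted p = 4.3e-04) and INSIG1 of -1.12 ± 0.15 (adjusted p = 6.2e-06). The differences were 1.71 for ABCA1, 0.65 for ABCG1, 2.36 for ANGPTL4, -0.82 for ACTB and 0.85 for VIM, each past the threshold, and 0.33 for SQLE (adjusted p = 0.0530) and 0.10 for MYLIP (adjusted p = 0.7496). HMOX1 had a difference of -1.84. Of 31 lists tested by camera 14 differed. Interferon genes differed by a median of 4.22 (adjusted p = 6.2e-25), NF-kB targets by 2.91 (2.6e-14), cell cycle genes by -1.68 (4.7e-18), cholesterol synthesis by -1.31 (2.1e-06), intermediate filaments, lamins and tubulins by -0.77 (3.3e-05) and heat shock proteins by -0.59 (0.00160). These 6 also passed with an estimated correlation, at adjusted p of 7.4e-05, 0.00354, 1.5e-04, 0.0382, 0.0102 and 0.0382. The actin list differed by -0.37 (adjusted p = 2.5e-05; adjusted p = 0.0934 with an estimated correlation), with 25 genes lower and 3 higher of 51, and 29 and 3 over the list alone. The median difference of NRF2 genes, -0.05, had a sign other than its test, which was not past the threshold (0.964).

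The fourth comparison asked whether the same genes changed in both lines. Of 12403 genes tested in both and not listed at 0 throughout a group, 37 were higher in both lines, where independent calls would give 24.5 (Fisher's exact test across genes, two-sided p = 0.00256, 0.00826 after Benjamini-Hochberg adjustment over 8 such tests). Lower in both were 8, against 3.40 (Fisher's exact p = 0.00524, adjusted 0.0105). Genes higher in THP-1 and lower in EA.hy926 numbered 2, against 3.74 (Fisher's exact p = 0.352, adjusted 0.492). The opposite pair numbered 25, against 22.2 (Fisher's exact p = 0.523, adjusted 0.597). Most of those 25 were histone genes, many of them near copies of each other, and genes are not independent replicates. Shared rises included CXCL8, TRAF1, ICAM1, RELB, TNFAIP3, CXCL2, SOD2, FTH1, CLDN1, MMP9, RND3 and ANGPTL4, and shared falls DHCR7 and SCD. The difference between the lines was -1.84 for DHCR7 and 1.06 for ST3GAL5. With genes listed at 0 included, 46 were higher in both against 32.1 (Fisher's exact p = 0.00310, adjusted 0.00826). The 13 lower in both were fewer than the 27.0 of independent calls (Fisher's exact p = 7.1e-04, adjusted 0.00565), unlike the 8 against 3.40 above. Together these 59 in the same direction are no excess over independent calls. Opposite pairs numbered 34 against 30.1 and 28 against 28.9. The total of 59 fell to 38 without EA.hy926 LDL replicate 2 and to 25 at a minimum mean of 50, and was 122 with all 12 libraries in one fit. Across the 12403 genes, the fold changes of both lines had a Pearson correlation of 0.0980 and a Spearman correlation of 0.0264, and 48.8% shared their sign. Across the 83 genes called in EA.hy926 they were 0.499 and 0.537.

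**Figure D3:**
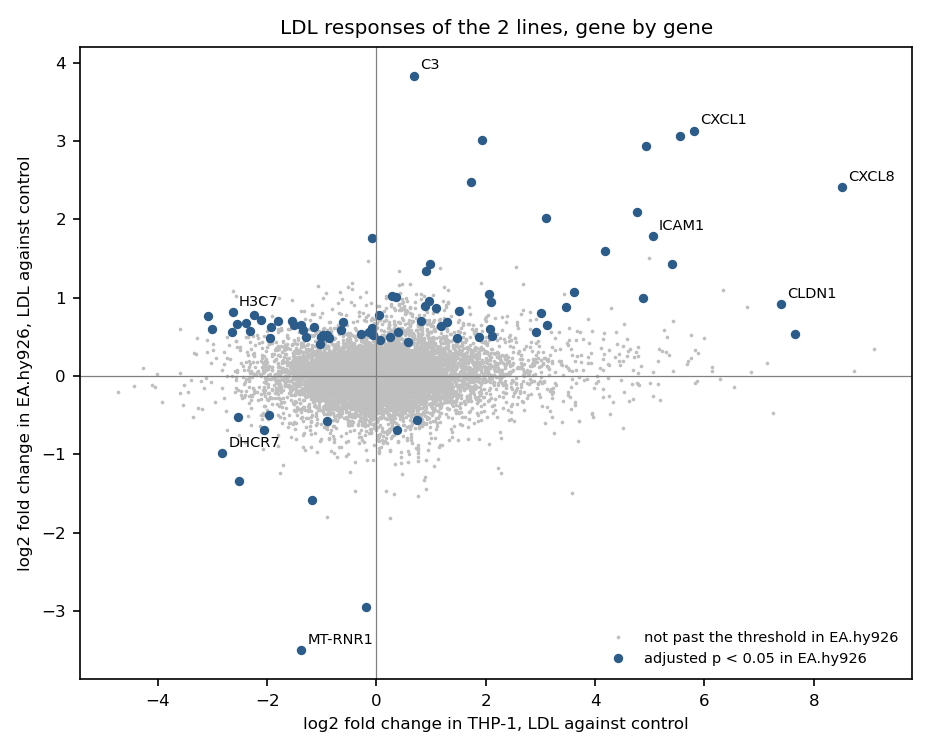
Log2 fold change with LDL in THP-1 (horizontal axis) and EA.hy926 (vertical axis) for the 12403 genes tested in both lines and not listed at 0 throughout a group, with the genes past the threshold in EA.hy926 in blue. The rises of EA.hy926 include CXCL8 (8.51 in THP-1, 2.41 in EA.hy926) and ICAM1 (5.05 and 1.79) on the right and the histone gene H3C7 (-2.63 and 0.81) on the left.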

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

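Of the tests in this part, those of the authors' filter, of switching at any level, of lymphocytes and of a contaminant were chosen only after the results were seen. Each result given here was picked out because the effect of LDL differed between THP-1 and EA.hy926 by a limma or camera test of the difference itself. Differences are THP-1 minus EA.hy926 on the log2 scale. The count of such genes was 5901. In 2 of 100 splits drawn from the 200 that regroup the libraries within each line, the real one included, the count was as large. The highest of the other splits gave 6300, with the real THP-1 groups and mixed EA.hy926 libraries. The 10 splits with the real THP-1 groups gave 5074 to 6300 against 0 to 70 for the other 90. The count thus follows the grouping of THP-1 alone, 1 of 10 possible, and these are too few for a share under 0.05.

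Larger rises in THP-1 gave differences of 8.76 for IFI44L, 8.67 for CD274, 7.12 for CCL2, 6.99 for P3H2, 6.80 for IFI27, 6.69 for HLA-DRA, and 6.10 for CXCL8. Smaller ones were 3.97 for CXCL2, 3.27 for ICAM1, 2.59 for TNFAIP3, 2.48 for TRAF1, 2.36 for ANGPTL4, 1.71 for ABCA1, 1.08 for RELB, 0.85 for VIM and 0.65 for ABCG1. Genes that fell in EA.hy926 gave 2.76 for MT-RNR2, 2.13 for MT-RNR1 and 1.06 for ST3GAL5. Negative differences were -0.82 for ACTB, -0.93 for HMGCS1, -1.12 for INSIG1, -1.84 for HMOX1 and -1.84 for DHCR7. Further ones were -3.98 for DYSF, -4.05 for BIN1, -4.19 for RFLNB, -4.37 for NRGN and -4.51 for MMRN2. Median differences of lists were 4.22 for interferon, 2.91 for NF-kB, 0.95 for the unfolded protein list, 0.79 for immediate early genes and 0.63 for hypoxia. They were -0.37 for actin, -0.52 for endothelial markers, -0.59 for heat shock proteins, -0.70 for oxidative phosphorylation, and -0.77 for intermediate filaments, lamins and tubulins. Further down were -1.11 for ribosomal proteins, -1.31 for cholesterol synthesis, -1.68 for cell cycle and -2.22 for mitochondrial mRNAs. With an estimated correlation 8 of these 14 calls were lost, at adjusted p of 0.0934 for the unfolded protein list, 0.486 for immediate early genes, 0.258 for hypoxia and 0.0934 for actin. It was 0.227 for endothelial markers, 0.0727 for oxidative phosphorylation, 0.210 for ribosomal proteins and 0.258 for mitochondrial mRNAs. The hypoxia difference was also lost without THP-1 LDL replicate 1 (camera adjusted p = 0.0803), EA.hy926 control replicates 1 (0.0530) or 2 (0.0504) or EA.hy926 LDL replicate 2 (0.05004), and with quantile normalization (0.141). So it was with no minimum mean (0.0792), a minimum of 50 (0.0568) and the RN7SL1 covariate (0.0653). That of immediate early genes was lost without EA.hy926 LDL replicate 3 (median difference 0.42, camera adjusted p = 0.0596) and that of endothelial markers at a minimum mean of 50 (0.136). For the 14 lists that differed, 11 of 100 splits gave as many and the highest other gave 21, so chance cannot be excluded for that number.

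Within a line, 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real split gave 10425 genes and 17 lists in THP-1 and the highest other gave 0 genes and 14 lists. In EA.hy926 the real split gave 285 genes and 13 lists and the highest other 1 gene and 7 lists. Each of these 4 results was reached in 1 of the 10 splits. For the 59 genes changed in the same direction in both lines, 2 of 100 splits gave as many and the highest other gave 62. That other split swaps the EA.hy926 labels and so counts the genes changed in opposite directions. The remaining 98 splits gave 0 or 1, since mixed groups call almost no genes, so just 2 splits bear on this count, too few for a share under 0.05.

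The first pattern is that 186 of the 285 EA.hy926 genes called by limma were listed at 0 throughout one group. Zeros by chance at this depth were argued against, since a Poisson count foresees 3.3e-08 such genes where 187 of those tested were seen. Switching by LDL at any level was argued against too: 0 of 10503 genes at 50 or more in one group were at 0 in the other (exact 95% upper limit 0.0351%), against 187 of 3699 below 50 (5.06%, 4.37% to 5.81%). The authors' filter and joining of gene lists may account for the zeros, since 168 genes at 10 to 15 in one group had 0 reads in the other and 0 had 1 to 6, but its rule is not known, and groups with a few reads were also kept, as with C3 at 0.752 in EA.hy926 control. A smaller change by LDL in each such gene stays open, because the reads behind a listed 0 are not in the values.

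The second pattern is the fall of the 43 ribosomal protein genes in THP-1. After a smooth trend on transcript length and GC was removed their median log2 fold change was -1.22 (before, -0.93) and the camera adjusted p 2.0e-16, which argues against that trend as the cause. The trend was fitted on other genes of every type and was weak (R squared 0.0094). It could hardly have undone the fall, since the shortest genes, of 61 to 540 bases, had a median of 0.52. The test thus bears on that trend alone and cannot exclude an effect of length confined to short mRNAs. A few abundant non-coding RNAs taking reads would lower all genes alike and are argued against by the list's distance of -1.01 from the median of all genes, and a general loss of abundant mRNA by the 200 most abundant other genes, whose median was 0.016. The estimated correlation of the list was 0.41, and camera with it gave an adjusted p of 0.199. Its genes may thus move together for a reason shared by fewer independent units than 43. An effect of LDL stays open as an untested biological explanation.

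The third pattern is the rise of the interferon and NF-kB lists in THP-1. Scaling is argued against by size alone: the lowest median of either list under 3 other scalings was 4.35 and the highest 4.64. Those scalings put the median of all genes at -0.08 to 0.01, against 0.08 as deposited, so they could hardly have undone such rises. Lymphocytes in the LDL libraries cannot be told apart from a response of THP-1, because just 2 markers were tested (median log2 fold change -0.077, 0 higher, TRAC -0.79); the first measure tried, the median level of the 3 markers in the table, went from 9.86 to 15.8 and met its criterion of 10. An inflammatory contaminant of the LDL, such as endotoxin, could give the same rise and cannot be told apart from LDL here: 3 of 3 endotoxin receptor genes (TLR4, CD14, LY96) were at 10 or more in THP-1 control libraries, which allows such a response and shows none. A response to LDL itself stays open, untested.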

How the results depend on the processing

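Genes listed at 0 left out and RN7SL1 as a covariate were chosen after seeing the data. In THP-1 this covariate follows treatment, so a call lost with it decides little. The cause of each move below was not tested unless the setting itself shows it. For THP-1, 6417 genes passed with the RN7SL1 covariate and 4501 with a minimum log2 fold change of 1, which admits fewer genes by construction. Other settings stayed within 1.5 times of 10425. For EA.hy926, 466 genes passed with no minimum mean, 45 with a minimum of 50, 473 with the 12 libraries in one fit, 48 with genes at 0 left out and 703 with the RN7SL1 covariate. The minimum of 50 and the omission of zeros remove the 186 genes at 0 by construction, but the 99 others fell to 45 and 48 as well. Genes changed in the same direction in both lines numbered 25 with the minimum of 50, 122 with one fit, 28 with genes at 0 left out and 160 with the RN7SL1 covariate. Of the count tests, edgeR called 10610, 294 and 6002 genes in THP-1, EA.hy926 and the difference, and DESeq2 9321, 336 and 5835. With a replicate block the counts were 10377, 231 and 5166 genes and 44 in the same direction, and of the 231 only 45 were not at 0 in a group. Replicates of the same number were not alike across groups (correlations of -0.13, -0.09 and 0.07 in THP-1 and -0.51, 0.06 and -0.42 in EA.hy926). Pairs with different numbers ran from -0.09 to 0.18 in THP-1 and from -0.25 to 0.59 in EA.hy926. The highest was EA.hy926 control replicate 1 with LDL replicate 3. A factor shared across the EA.hy926 groups under other numbers is therefore not excluded, and a block by number would not remove it.

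With 1 library left out, where the reduced group keeps 2, THP-1 counts ran from 9174 to 10446, EA.hy926 counts from 220 to 341, differences from 5208 to 5906 and genes in the same direction from 38 (without EA.hy926 LDL replicate 2) to 86. Lists past the threshold ran from 16 to 18 in THP-1, from 7 to 13 in EA.hy926 (7 without control replicate 3, 8 without control replicate 2) and from 13 to 15 for the difference. The median of cholesterol synthesis in THP-1 ran from -1.30 to -1.19 and that of actin from -0.39 to -0.35 (-0.83 with quantile normalization). In EA.hy926 they ran from -0.11 to 0.06 and from -0.02 to 0.08. The median of the EA.hy926 ribosomal protein list ran from 0.0066 to 0.21, and without LDL replicate 3 its test turned down (median 0.0086, camera adjusted p = 0.986).

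Reversed with quantile normalization in THP-1 were MSR1 (-0.038), RN7SL1 (-0.31) and SQLE (-0.33) (log2 fold changes), and the cause was not tested. Over all alternatives the named genes kept their side of the threshold in 6894 comparisons, lost the call in 148, gained it in 115 and reversed in 3. The lists did so in 1920, 55, 38 and 1. A change of sign was counted as reversed only where at least 1 of the fits compared passed the threshold. The kept comparisons can therefore include changes of sign without a call. Control levels moved by more than 1 SD in 12 comparisons and by less in 463. RN7SL1 itself was not run under its own covariate, which would void its test.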

Other observations

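The test of S phase cells in this part was chosen only after the result was seen, as was the list of histone genes; that of CH25H was chosen once the lists had been seen, before its own values were. Genes of the replication-dependent histones, which package new DNA, went in opposite directions in the lines. In EA.hy926 54 of 55 measured genes had a positive log2 fold change, 20 passed the threshold of limma as higher and 0 as lower, with a median of 0.48. H3C7 stood at 1031, 986 and 939 normalised counts in the EA.hy926 control libraries and at 2018, 1536 and 1667 with LDL, and H2AC13 at 716, 744 and 674 and at 1434, 1113 and 1117. In THP-1 48 of 54 were lower and 4 higher past the threshold, with a median of -1.80, and H3C7 went from 1245, 1364 and 1367 to 244, 160.3 and 248. The medians kept their sign under all 4 scalings, from -1.94 to -1.80 in THP-1 and from 0.44 to 0.48 in EA.hy926. In the test of the difference 46 of 53 were lower in THP-1 past the threshold, with a median of -2.36. Camera gave p = 2.2e-40 in EA.hy926, 4.4e-20 in THP-1 and 3.4e-31 for the difference, and p = 0.0224, 0.0492 and 0.00861 with an estimated correlation, for a list picked because it showed the pattern. Many of these genes are near copies of each other, so reads may be assigned to the wrong member, and most of their mRNAs lack a poly(A) tail, so their level may also follow how the library was made. A candidate explanation is a change in the share of cells in S phase. The S and M phase list fell with the histones in THP-1 (median -1.59), but in EA.hy926 its median was 0.07 and its camera adjusted p 0.188, which does not decide the matter. A first reading counted that p against the explanation, and was changed because a p past no threshold decides neither.

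The mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2 fell in EA.hy926, MT-RNR1 from 619, 1570 and 692 to 138, 82.1 and 39.2 normalised counts and MT-RNR2 from 1119, 1902 and 1034 to 307, 176 and 86.2. Of the 13 mitochondrial mRNAs 0 passed the threshold of limma, and no shared rise of them is claimed: the list had a median log2 fold change of 0.36 (camera adjusted p = 0.00447; 0.589 with an estimated correlation). Without single libraries that median ran from 0.14 to 0.64, and the call was lost in 2 of 6 fits. In THP-1 all 13 mitochondrial mRNAs fell (median -1.75), while MT-RNR2 went from 149 ± 109 to 113 ± 31.3 (SD of 3 libraries; limma adjusted p = 0.679) and MT-RNR1 from 62.1 ± 30.5 to 23.7 ± 13.0 (adjusted p = 0.00753, a call lost without control replicate 3 at 0.0578 and with the RN7SL1 covariate at 0.767). Levels of ribosomal RNA in such libraries depend on how it was removed, for which the sources used here give no account.

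A hypothesis for the fall of cholesterol synthesis genes in THP-1 is 25-hydroxycholesterol, an inhibitor of SREBP made by CH25H, itself an interferon-induced gene. Its test asked whether CH25H was higher with LDL. It went from 32.9 ± 7.38 to 53.7 ± 9.57 normalised counts, a log2 fold change of 0.70 (limma adjusted p = 0.0156), as the hypothesis needs. The call is a weak one: it was lost without control replicate 1 (adjusted p = 0.0679), control replicate 2 (0.0632) or LDL replicate 2 (0.0518), with quantile normalization (0.0789), in DESeq2 (0.0691) and with the RN7SL1 covariate (0.0729). In these fits its log2 fold change was 0.59, 0.63, 0.57, 0.46, 0.64 and 1.18, in that order. Cholesterol delivered by LDL lowers the same genes. The design may not separate the 2 sources, since every THP-1 LDL library received LDL and neither sterol is among the values used here.

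A few genes of complement and inflammation that stood near the floor in EA.hy926 control libraries also rose there, chosen after their values were seen. C3 went from 0.752 ± 0.652 to 23.4 ± 7.74, CXCL1 from 4.01 ± 1.30 to 42.4 ± 7.97, TNFRSF9 from 1.79 ± 1.60 to 18.3 ± 2.58 and BIRC3 from 2.55 ± 0.656 to 27.5 ± 11.8 normalised counts (SD, n = 3 per group), and all 4 passed limma in THP-1 as well, with log2 fold changes of 0.69, 5.80, 1.94 and 4.93.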
